A study of Homo sapiens with 9 samples.

How the data were processed

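RNA from cultured human epidermal keratinocytes was measured on 9 Affymetrix HG_U95Av2 arrays, which read each gene with 1 or more sets of short probes. Interferon gamma (IFNg), a cytokine of activated lymphocytes, had been added to 4 cultures for 1, 4, 24 or 48 h, and 5 arrays held untreated cells at 1 h (2 arrays), 4 h, 24 h and 48 h. Per the labels, treated cells had first been moved from the medium named KGM to the medium named KBM for 24 h, and the untreated arrays also served as controls for other cytokines that are not analysed here. The labels do not say that the treated and untreated cultures came from the same cells, and nothing says that the 2 untreated arrays at 1 h came from separate cultures beyond the words for a second batch. The p-values therefore measure only the spread between these arrays, and that of the untreated 1 h pair may be technical. Only this pair repeats a condition, so the rest of the residual spread comes from differences between time points. A gene whose response varies with time is thus less likely to pass. The label of the untreated 48 h array also carries a note of a second label.

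The deposited values are probe set intensities on a linear scale, which the labels of the untreated arrays call Signal or normalised Signal. The software that made them, its version and its detection calls are not given in the sources used here. Tested on the values, each deposited array had a 2% trimmed mean intensity of about 150 (150.04 to 150.16), and medians ran from 36 to 46.6. The table held 12625 probe sets, 67 of them Affymetrix controls, and 20 probe sets had an empty cell on at least 1 untreated array and were left out. Array run files were used only to see which arrays shared a scan day and a chip lot. The 4 treated arrays were scanned on 1 day and 4 of the untreated arrays on another, all 8 were of 1 chip lot, and the second untreated 1 h array had no run file here. Scan day and treatment cannot be told apart, so a fit with scan day as a block could not be made.

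Genes were named from the platform annotation, in which 10961 probe sets had 1 gene symbol, 545 had several and 1119 had none, for 8229 symbols in all. Of the probe sets with 1 symbol, 10949 matched a gene of the RefSeq table by gene number. Probe sets with several symbols were not named. A further 16 probe sets were left out under a rule on human records. No genome build is named for the array files, so no coordinates are given.

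Intensities were quantile normalised over the 9 arrays, scaled to a 2% trimmed mean of 500, floored at 100 and put on the log2 scale. The floor corresponds to 30.02 and the filter below to 60.05 in deposited units. Probe sets that reached 200 on at least 2 arrays were kept, with 1 probe set per gene (the one with the highest mean), which left 4671 genes. Fold changes of dim genes are understated by the floor. Where all untreated or all treated arrays of a time point lay at or below the floor, the ratio is given as "at least".

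Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, Benjamini-Hochberg adjusted p below 0.05). The treatment effect over all times was fitted with the time point as a block (4 residual degrees of freedom). Early (1 and 4 h) and late (24 and 48 h) effects and their difference came from a model with separate early and late effects (3 residual degrees of freedom). Late against early untreated cells came from a model of the 4 combinations of treatment and period (5 residual degrees of freedom). With 1 treated array per time point, ratios at single times were tested only in a model with 1 residual degree of freedom that was added later, and the difference between the 2 untreated 1 h arrays is given as the array-to-array spread. The number of arrays limits the precision of every value.

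Before the data were examined, 24 gene lists were fixed, including markers of fibroblasts, melanocytes, leukocytes with Langerhans cells, and endothelial cells, and 22 had at least 2 measured members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry as alternatives. At single times, a list's median ratio was placed among 10000 random lists of the same size matched on mean expression in 10 bins. Genes to be named were fixed by rule: for the all-times and late comparisons, the 12 largest changes each way past the threshold with the same sign at every time of the comparison. For the early, late-minus-early and untreated time comparisons, the 6 largest each way were named. Up to 4 members of each list with the largest mean log2 ratio in size over the 4 times were named, and at each time the 3 largest ratios each way.

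The fits were tested on simulated data with 4671 genes. For the all-times effect, 61.2% of genes changed by 1 log2 unit, 98.5% of those changed by 2 and 100% of those changed by 4 were recovered. For the late effect the shares were 7.46%, 83.6% and 97.0%, and for the untreated time comparison 26.9%, 82.1% and 100%. False calls numbered 6, 6 and 11 in the same order. The simulated changes were equal at all times of a comparison, so these shares do not hold for genes whose response varies with time.

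Alternatives covered other scalings, floors, filters, probe set rules, spread estimates, a fit without the time block, and leaving out each array in turn. A fit without the treated 4 h and 48 h arrays and a model with an effect of its own at each time were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.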

Results

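Expression of 4671 genes was compared between keratinocytes, the main cell of the epidermis, kept with interferon gamma (4 arrays, 1 each at 1, 4, 24 and 48 h) and untreated keratinocytes (5 arrays, 2 at 1 h and 1 each at 4, 24 and 48 h). The question was which genes respond to this cytokine in keratinocytes, and when. Between 41.8% and 45.3% of probe sets reached a scaled intensity of 200 on each array. The 2 untreated 1 h arrays differed across genes by a log2 SD of 0.44, with 76 genes more than 2-fold higher and 100 more than 2-fold lower on the second. Treated over untreated ratios had a log2 SD of 0.43 at 1 h, 0.87 at 4 h, 0.94 at 24 h and 1.02 at 48 h.

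Over the 4 time points, IRF1, a transcription factor induced by interferons, was the gene that passed the test. Its scaled intensity was 328 ± 94.9 (SD, n = 5) without and 4603 ± 1233 (SD, n = 4) with interferon gamma. IRF1 rose by a log2 of 3.76 ± 0.26 (SE, limma adjusted p = 0.00399), being 8.69-fold higher at 1 h, 10.2-fold at 4 h, 22.6-fold at 24 h and 19.4-fold at 48 h, against 0.938-fold between the 2 untreated 1 h arrays. No gene passed in the lower direction, and 1070 of 4671 genes had an unadjusted p below 0.05, where chance alone gives 234. PMAIP1 (log2 2.04 ± 0.23, SE, adjusted p = 0.0526), a cell death gene, and KLF6 (log2 1.30 ± 0.18, SE, adjusted p = 0.0737), a transcription factor, lay above the threshold although their ratios were positive at every time, with PMAIP1 3.14-fold to 5.60-fold higher. Without the treated 1 h array, 181 genes passed, 121 higher and 60 lower, and without the treated 4 h and 48 h arrays none did (limma, 502 at an unadjusted p below 0.05).

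The list of interferon gamma core response genes shifted upward over the 4 time points, with a mean log2 of 2.09 over 27 measured genes, 25 of them positive (camera adjusted p = 1.10e-14). Adjusted over the list alone, 23 genes rose and none fell, against 1 when adjusted over all genes tested. Antiviral and type I interferon genes (29 measured, mean log2 0.94, camera adjusted p = 2.76e-07), chemokines and cytokines (19 measured, mean log2 1.84, camera adjusted p = 3.81e-06) and MHC class I genes with their peptide loading partners (14 measured, mean log2 0.89, camera adjusted p = 7.02e-05) shifted the same way. Adjusted over the list alone, 16 antiviral genes, 10 chemokines and cytokines and 6 genes of the MHC class I list rose, and none fell. That list, called MHC class I genes for short, includes peptide loading genes such as TAP1, PSMB8, PSMB9 and PSMB10. These were its members with the largest mean ratios. For each of these 4 lists the adjusted p was 0.687 with an estimated correlation. The self-contained fry test gave an unadjusted p of 0.0151 for the core list, 0.0238 for the antiviral list, 0.0429 for chemokines and 0.111 for MHC class I, and no list passed after adjustment. The filter can keep a gene that is dim in untreated cells through treated arrays alone, which raises list means. Of 31 chemokine and cytokine genes on the array, 19 were kept. Without a filter the mean log2 of that list was 1.16 over the 4 time points, 1.06 early and 1.29 late.

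Chemokines that attract T cells had the largest ratios at 48 h. All 5 untreated arrays lay below the floor for CXCL9, CXCL10 and CXCL11. CXCL11 was at least 5.62-fold higher at 1 h and at least 183.3-fold higher at 4 h, 127.7-fold at 24 h and 85.4-fold at 48 h. CXCL10 was at least 4.19-fold higher at 1 h and 132.4-fold at 4 h, and CXCL9 at least 3.32-fold and 183.9-fold. These genes did not pass over the 4 time points (limma adjusted p = 0.0762 for CXCL11 and 0.102 for CXCL9 and CXCL10). Without the treated 1 h array they did, with a log2, bounded by the floor, of at least 7.13 ± 0.27 (SE, adjusted p = 2.51e-04) for CXCL9, 6.99 ± 0.25 for CXCL11 and 6.62 ± 0.29 for CXCL10. Among the fits that left out 1 array that fit was the most favourable, with 181 genes called against 1 in each of the others. In that fit 18 of 27 core genes, 12 of 29 antiviral genes, 6 of 19 chemokines and cytokines and 4 of 14 MHC class I genes rose. Among them were ICAM1 (log2 at least 6.03), a leukocyte adhesion molecule, and the chemokine CCL2 (at least 5.44), both below the floor on all 5 untreated arrays. The 4 of the MHC class I list were the peptide transporter TAP1 (3.40) and the immunoproteasome subunits PSMB9 (3.07), PSMB8 (1.90) and PSMB10 (1.52). These counts overlap, because lists share members. TAP1, PSMB8, PSMB9, CXCL9, CXCL10, CXCL11 and the antiviral gene TRIM22 were also counted among the core genes.

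**Figure D1:**
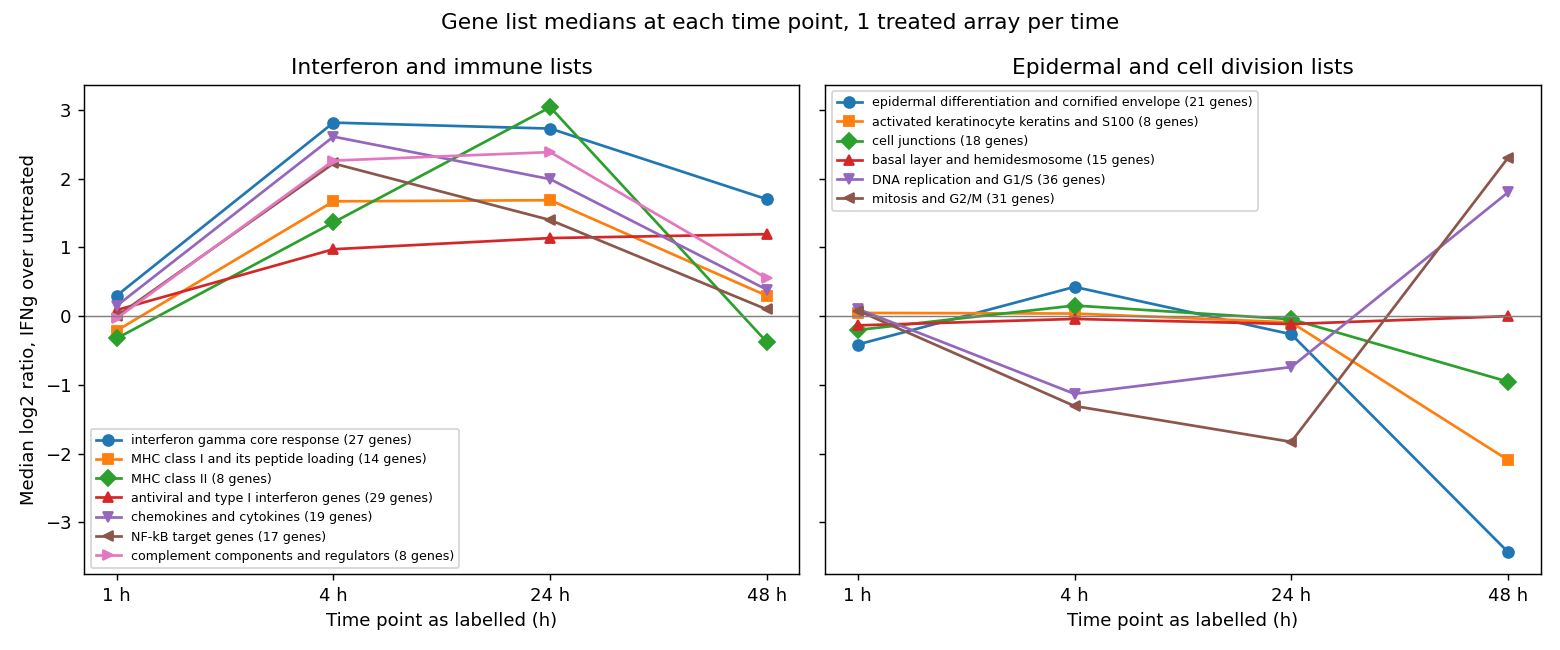
Median log2 ratio of treated over untreated arrays for the members of 13 gene lists at each time point as labelled, with the number of measured genes in the key and 1 treated array per time. The core interferon list stood at 0.30, 2.81, 2.73 and 1.70 at 1, 4, 24 and 48 h, and the differentiation list at -3.43 at 48 h (-1.38 with the mean of all untreated arrays as reference).

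At 1 h, 5 of 27 core genes were more than 2-fold higher, against 22 at 4 h, 22 at 24 h and 20 at 48 h. The antiviral list had medians of 0.09, 0.97, 1.14 and 1.19 in log2 at 1, 4, 24 and 48 h, and IFIT2, whose product binds viral RNA, was 2.26-fold, 3.12-fold, at least 10.3-fold and 32.7-fold higher. MHC class II genes, which present antigen to helper T cells, had medians of -0.32, 1.36, 3.04 and -0.38. With intensities as deposited, on which the same floor and filter are stricter, the medians were 0, 3.02, 4.13 and 0. HLA-DRA was 16.2-fold higher at 4 h and 30.1-fold at 24 h but 0.889-fold at 48 h, and the invariant chain gene CD74 was 21.3-fold, 18.3-fold and 0.446-fold of untreated. The class II list did not pass over the 4 time points (8 measured, 7 positive, camera adjusted p = 0.113). All ratios at single times rest on the time labels of the treated arrays, which may have been exchanged, as set out below.

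NF-kB target genes (17 measured, mean log2 1.07, camera adjusted p = 2.69e-04) and complement genes (8 measured, mean log2 0.95, camera adjusted p = 0.0256) also shifted upward. Adjusted over the list alone, 4 NF-kB targets and 5 complement genes rose and 1 complement gene fell, and none passed over all genes. Both had an adjusted p of 0.687 with an estimated correlation. Their medians at 4 h were 2.22 and 2.26, and at 48 h 0.10 and 0.55. TNFAIP3, a brake on NF-kB signalling, was 7.94-fold higher at 4 h and 2.62-fold at 48 h. The complement genes SERPING1, C1R and C1S were 11.8-fold, 16.8-fold and 12.1-fold higher at 4 h, and 2.42-fold, 1.78-fold and 0.911-fold at 48 h. Apoptosis and growth arrest genes (18 measured, mean log2 0.39, camera adjusted p = 0.0217) included CASP8, which was 1.45-fold to 2.84-fold higher, and CDKN1C, an inhibitor of cell cycle kinases, which was 1.38-fold to 7.92-fold lower. Constitutive proteasome subunits (23 measured) had a mean log2 of 0.21 (camera adjusted p = 0.0256), and cytosolic ribosomal proteins (39 measured) a mean of -0.16 (camera adjusted p = 0.0033). Epidermal differentiation genes (21 measured, 19 of them negative) had a mean of -0.93 (camera adjusted p = 9.51e-04), which was -0.17 without the treated 48 h array (adjusted p = 0.363) and -0.15 without the untreated 48 h array (adjusted p = 0.427). The adjusted p of these 4 lists was 0.687 with an estimated correlation. Adjusted over the list alone, 5 apoptosis genes rose and 1 fell, and none of the members of the other 3 lists passed. Without the treated 4 h array the NF-kB, complement, apoptosis and ribosomal means were 0.67, 0.67, 0.31 and -0.12, and their calls were lost (adjusted p = 0.0990, 0.0869, 0.0670 and 0.0670). The complement mean was 0.60 without the treated 24 h array (0.0990) or the untreated 24 h array (0.115). Without the treated 48 h array the proteasome mean was 0.09 (0.293), and without the treated 24 h array the ribosomal mean was -0.07 (0.161).

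**Figure D2:**
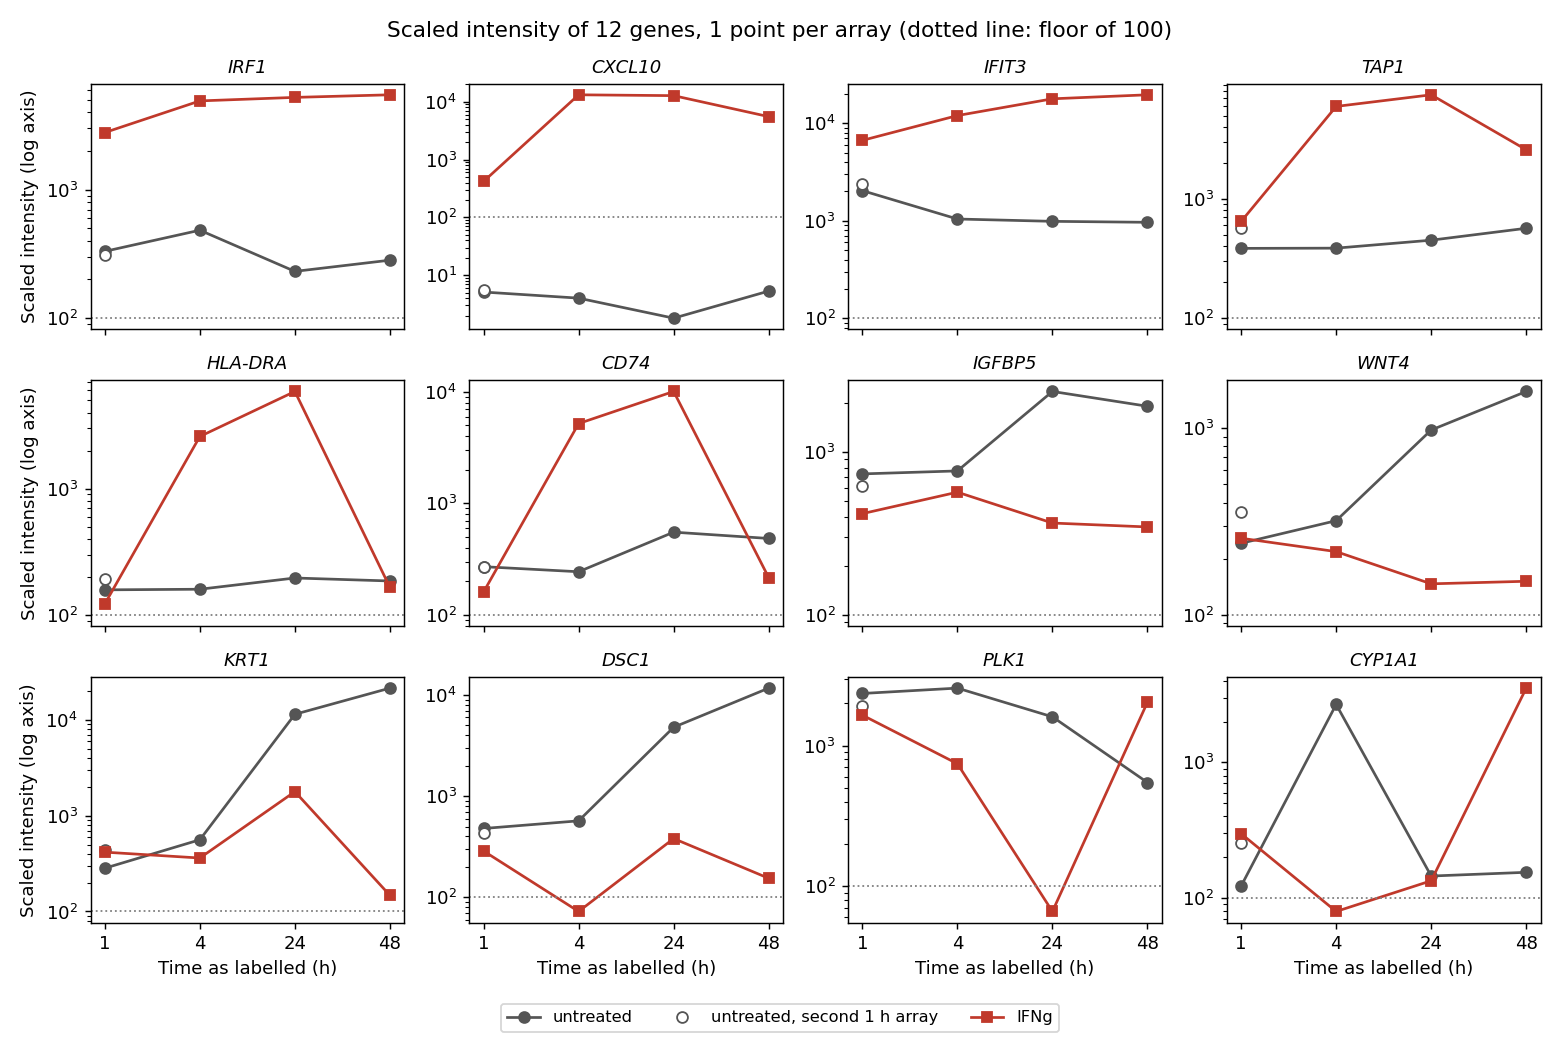
Scaled intensity on a log axis against time as labelled for 12 genes, with 1 point per array, circles for untreated and squares for IFNg arrays, and the floor of 100 as a dotted line below which values entered the tests at 100. IRF1 lay between 2787 and 5481 on treated and between 231.3 and 483.9 on untreated arrays, whereas HLA-DRA stood at 2589 and 5887 on the treated 4 h and 24 h arrays and at 164.9 on the 48 h array.

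The early effect (1 and 4 h) again gave 1 gene, IRF1, which rose by a log2 of 3.22 ± 0.22 (SE, limma adjusted p = 0.0175). No gene fell, and 243 genes had an unadjusted p below 0.05. The core interferon list had a mean log2 of 1.61 (camera adjusted p = 3.49e-15), chemokines and cytokines 1.62 (1.82e-07), antiviral genes 0.62 (3.77e-06), NF-kB targets 1.08 (2.19e-05) and MHC class I genes 0.71 (1.20e-04). Each had an adjusted p of 0.610 with an estimated correlation. Adjusted over the list alone, 4 core genes, 2 chemokines and cytokines and 1 antiviral gene rose, against 1 gene, IRF1, over all genes. Complement genes (mean log2 0.81, camera adjusted p = 0.042) and apoptosis genes (0.33, 0.0472) were shifted upward and ribosomal proteins (-0.12, 0.0262) and mitosis genes (-0.48, 0.0404) downward, with adjusted p values of 0.610 for the first pair and 0.817 for the second with an estimated correlation. The mitosis call was also lost with trimmed-mean scaling (adjusted p = 0.0755) and without a filter (0.101), and without the treated 4 h array the mitosis mean was 0.15, the class I mean -0.06 and the ribosomal mean 0.01. With arrays left out the core mean ran from 0.53 to 3.04 and the chemokine mean from 0.48 to 3.13, and the chemokine call was lost without the treated 4 h and 48 h arrays (0.0576). Without the treated 4 h array the antiviral, NF-kB, complement and apoptosis means were 0.13 (adjusted p = 0.447), 0.06 (0.865), 0.07 (0.865) and 0.09 (0.865), and without the untreated 4 h array 0.13 (0.510), 0.13 (0.626), 0.11 (0.626) and 0.09 (0.771). The count of 1 gene was 3 without the treated 1 h array, and 0 without the treated 4 h array, the untreated 4 h array or either untreated 1 h array.

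The late effect (24 and 48 h) took in 7 genes. IRF1 (log2 4.39 ± 0.24, SE, limma adjusted p = 0.00397), IFIT3 (4.26 ± 0.46, 0.0428), IFIT2 (4.20 ± 0.42, 0.0428) and ETV4 (2.62 ± 0.28, 0.0428) rose. WNT4 (-3.06 ± 0.32, 0.0428), IGFBP5 (-2.57 ± 0.25, 0.0428) and BCAM (-2.21 ± 0.24, 0.0431) fell. ETV4 is a transcription factor of the ETS family, WNT4 a secreted signalling protein, IGFBP5 a binding protein of insulin-like growth factors and BCAM a laminin receptor. Untreated ETV4 went from 739.5 to 1027 at 1 and 4 h to 117.7 and 106.0 at 24 and 48 h, while the treated arrays stayed between 652.4 and 872.6. Untreated WNT4 stood at 241.8 to 354.0 early and at 978.7 and 1576 late, and treated WNT4 at 146.6 and 151.3 late. A total of 968 genes had an unadjusted p below 0.05. The count of 7 was 25, 21, 66 and 0 without the treated 1, 4, 24 and 48 h array. It was 17, 19 and 1 without the untreated 4, 24 and 48 h array, and 0 without either untreated 1 h array.

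Among the lists, the core (mean log2 2.66, camera adjusted p = 3.03e-12), antiviral (1.32, 9.05e-08), chemokine (2.09, 7.30e-04) and MHC class I genes (1.10, 0.00152) were higher late, and epidermal differentiation and cornified envelope genes were lower (-1.96, 1.18e-07, 21 measured). These 5 lists each had an adjusted p of 0.716 with an estimated correlation. The differentiation mean was -0.44 without the treated 48 h array (camera adjusted p = 0.0954) and -0.39 without the untreated 48 h array (0.133). The chemokine and MHC class I calls were lost without the treated 24 h array (0.299 and 0.681) or the untreated 24 h array (0.361 and 0.626). NF-kB targets (1.06, 0.0188), apoptosis genes (0.46, 0.0394) and proteasome subunits (0.34, 0.0152) shifted upward and ribosomal proteins (-0.20, 0.0188) downward, with adjusted p values of 0.791, 0.716, 0.727 and 0.823 with an estimated correlation. Without the treated 24 h array the NF-kB mean was 0.32 (0.976), the apoptosis mean 0.28 (0.661) and the ribosomal mean 0.04, which was 0.04 without the untreated 24 h array too, and without the treated 48 h array the proteasome mean was 0.09 (0.539). Adjusted over the list alone, 8 differentiation genes fell and 19 core, 12 antiviral, 5 chemokine and 3 MHC class I genes rose. Over all genes tested, 1 core and 2 antiviral genes did, and no differentiation gene fell. At 24 h, 5 of 21 differentiation genes were more than 2-fold lower and 1 was higher (list median -0.26, or 0.63 with the mean of all untreated arrays as reference), and at 48 h 19 were lower. Of the named members, DSC1, KRT1, CRABP2 and DSG1 were 12.6-fold, 6.42-fold, 3.96-fold and 1.95-fold lower at 24 h. At 48 h they were 76.3-fold, 146.1-fold, 16.1-fold and at least 33.2-fold lower. The 18S rRNA control probe read 147.6 on the untreated 24 h array and 696.4 on the untreated 48 h array, and 30.7 or less on the other 7. COL1A1, a collagen gene of fibroblasts, read 327.7 and 654.1 on the same 2 arrays and between 92.1 and 120.2 on the others, and 1 of 3 fibroblast markers was lower late when adjusted over the list alone.

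No gene passed the test of the late minus the early effect, and 205 genes had an unadjusted p below 0.05 where chance gives 234. The gene lists did differ by camera. Differentiation genes had a mean log2 difference of -1.91 (camera adjusted p = 2.71e-10), activated keratinocyte keratins and S100 genes -1.25 (0.00433) and cell junction genes -0.49 (0.0141). The core interferon list (1.05, 1.33e-04), the antiviral list (0.70, 6.43e-05), DNA replication genes (0.78, 0.00124), mitosis genes (0.76, 0.00635) and proteasome subunits (0.24, 0.0298) differed upward. With an estimated correlation the adjusted p was 0.922 for mitosis genes and 0.907 for the other 7 lists. Without the treated 48 h array the differentiation, mitosis and replication differences were -0.39 (camera adjusted p = 0.0378), -1.21 and -0.43, and without the untreated 48 h array -0.35 (0.0790), -1.15 and -0.45. Activated keratinocyte and junction differences were -0.22 (0.178) and -0.01 (0.736) without the treated 48 h array, and both calls were lost without a filter (0.0849 and 0.0590). The proteasome difference was -0.0113 without either the treated or the untreated 48 h array. Without the treated 1 h array the core and antiviral differences were -0.38 and 0.04 (0.599), without the treated 24 h array the core difference was 0.65 (0.259), and without the treated 4 h and 48 h arrays the differentiation difference was -0.16 (0.961).

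Cell division genes took opposite directions at the single times. Of 31 mitosis genes, 23 were more than 2-fold lower at 4 h and 21 at 24 h, and 30 were more than 2-fold higher at 48 h. Of 36 replication genes, 19 and 14 were more than 2-fold lower and 28 more than 2-fold higher. The mitotic kinase gene PLK1 was 3.45-fold lower at 4 h, at least 16.0-fold lower at 24 h and 3.73-fold higher at 48 h, and CDC20, an activator of the anaphase-promoting complex, was 3.69-fold lower, 11.3-fold lower and 6.68-fold higher. The treated 48 h array read 2036 for PLK1, and untreated arrays read 1927 to 2564 at 1 and 4 h and 546.4 at 48 h. List medians for mitosis were 0.08, -1.31, -1.83 and 2.30 at 1, 4, 24 and 48 h, at the percentiles 75.3, 0, 0 and 100 among random lists. Between the 2 untreated 1 h arrays the list had a median of 0.21 at the percentile 99.5. An extreme percentile can thus arise without treatment. With the mean of all untreated arrays as reference the treated medians were 0.65 at 1 h, -0.82 at 4 h and 0.75 at 48 h. None of the division genes passed the test over the 4 time points.

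**Figure D3:**
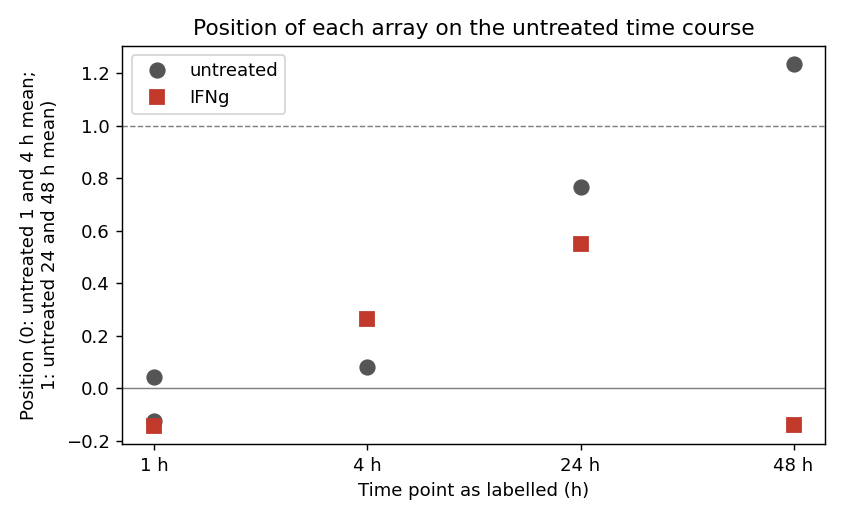
Position of each array along the difference between untreated late and early cells, taken over 426 genes that differed by more than 1 log2 unit, against the time as labelled (0 is the mean of untreated 1 and 4 h arrays and 1 that of untreated 24 and 48 h arrays). The treated 24 h array stood at 0.55 and the treated 48 h array at -0.14, beside -0.14 for the treated 1 h array.

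In untreated cells, late (24 and 48 h, n = 2) against early (1 and 4 h, n = 3), ETV4 changed by a log2 of -2.94 ± 0.22 (SE, limma adjusted p = 0.00254). No gene rose, and 726 genes had an unadjusted p below 0.05. Differentiation genes as a list were higher late (21 measured, all 21 positive, mean log2 2.29, camera adjusted p = 5.77e-13), and 13 of them rose when adjusted over the list alone. Junction genes (0.53, 0.0347) and activated keratinocyte genes (1.31, 0.0347) were also higher, and replication genes (-1.14, 3.13e-07), mitosis genes (-1.31, 6.25e-07) and proteasome subunits (-0.29, 0.00448) lower. The adjusted p was 0.926 for each of these 6 lists with an estimated correlation. The junction and activated keratinocyte calls were lost without a filter (0.140 and 0.208) and without the first untreated 1 h array (0.0637 and 0.0776). The junction call was also lost without the untreated 48 h array (0.0639) and the activated keratinocyte call without the untreated 24 h array (0.252), and the proteasome mean was -0.14 (0.165) without the untreated 48 h array. The 18S rRNA control probe and COL1A1 also read higher on the untreated late arrays, as given above, and 1 of 3 fibroblast markers was higher late when adjusted over the list alone. KRT1, a keratin of differentiating layers, read 283.0, 433.4 and 561.0 on the early untreated arrays, 11458 at 24 h and 21502 at 48 h (log2 5.26, adjusted p = 0.136). The desmosomal cadherin DSC1 read 429.2 to 568.9 early and 4803 and 11723 late (log2 3.94, adjusted p = 0.0747). The count of 1 was 2, 18 and 0 without the untreated 1 h (first array), 24 h and 48 h array. It was 19 without the treated 24 h or 48 h array and 132 without the treated 4 h and 48 h arrays, which enter through the shared spread.

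At single time points the largest floored ratio at 1 h after IRF1 and CXCL11 was that of PMAIP1 (4.35-fold higher). The 1 h ratios of CXCL9 and CXCL10 are lower bounds, so their rank stays open. The smallest floored ratios at 1 h were those of HES1 (3.93-fold lower), DLX2 (at least 3.14-fold lower) and UBE2H (at least 3.13-fold lower). HES1 is a target of Notch signalling. At 4 h and 24 h IL32, a cytokine gene, was at least 216.8-fold and 276.5-fold higher, but the untreated arrays lay near or below the floor, and at 48 h it was at least 1.53-fold higher. IGFBP3 was 12.7-fold lower at 4 h and 46.0-fold lower at 24 h, FGFR2 12.1-fold and at least 10.5-fold lower, and the basal keratin KRT15 14.3-fold lower at 24 h. CYP1A1, an enzyme induced through the aryl hydrocarbon receptor, was at least 26.7-fold lower at 4 h, and NOTCH3 was at least 68.2-fold lower at 48 h. The untreated 4 h array lay far above the other untreated arrays for CYP1A1 and FGFR2 (log2 signal 11.38 and 10.75). Their 4 h ratios therefore rest on that array. For CYP1A1 the treated 48 h array also read high, as given at the end. For this gene a distant untreated array and exchanged time labels of treated arrays cannot be told apart. A model with an effect of its own at each time had 1 residual degree of freedom and called 0 genes at every time with limma. At an unadjusted p below 0.05 it gave 319, 877, 1006 and 1322 genes at 1, 4, 24 and 48 h. Across genes, the ratios at 4 h and 24 h correlated at r = 0.76, those at 1 h and 48 h at 0.40, those at 24 h and 48 h at 0.32, those at 1 h and 24 h at 0.26, and both those at 1 h and 4 h and those at 4 h and 48 h at 0.13. Genes are not independent replicates.

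Markers of other cell types were scarcely measured, with 3 fibroblast, 2 leukocyte, 1 endothelial and 0 melanocyte genes kept. The fibroblast list did not pass over the 4 time points (camera adjusted p = 0.589). The leukocyte list did not pass either (camera adjusted p = 0.991), and ENG was 0.952-fold to 1.34-fold of untreated. The 3' over 5' intensity ratio, a sign of RNA integrity, ran from 1.03 to 1.25 for GAPDH and from 1.15 to 1.39 for ACTB. Spike-in controls were near absent on the untreated 24 h array, with 2.4 for BioB against 326.4 to 864.6 on the other 8 arrays.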

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

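The regroupings of arrays were planned before the data were examined, and the tests of time labels, RNA quality, scaling and scan day were chosen only after the results were seen. For each of 248 sets of values, the array lowest or highest in its group was compared with the rest of its group. In 21 cases such an array lay far from the others, and a rate of 1 in 20 would give 12.4. That rate cannot be relied on for dim genes, because arrays at or below the floor entered with the same value. For RSAD2, CXCL2 and MMP9, 4 of the 5 untreated arrays did so. The 21 cases against 12.4 are therefore no measure of an excess.

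Among array measures of the 5 untreated arrays, the deposited median of the 1 h array was the lowest at 42.4, and the 18S rRNA probe of the 48 h array was the highest at 696.4. The 48 h array was also lowest in the mean log2 signal of the sterol synthesis list (10.48) and of the matrix protease list (9.33). For single genes in log2 signal, the untreated 48 h array was highest for RSAD2 (6.84), CFB (7.14) and ATF3 (7.85) and lowest for PSMA5 (7.54). The untreated 4 h array was highest for TNFAIP3 (9.93), CXCL2 (6.91), CFLAR (7.86), CYP1A1 (11.38) and FGFR2 (10.75), and the untreated 24 h array for IL32 (6.74). The second untreated 1 h array was lowest for SERPING1 (8.60) and RPL10A (12.98) and highest for MMP9 (7.55). Among the 4 treated arrays, the 1 h array was lowest for IRF1 (11.44) and highest for PSMC6 (9.68) and PSMA2 (11.75), and the 4 h array was highest for COL1A1 (6.91).

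A difference between the late and the early effect was tested with camera for every list. It passed for the core interferon (1.05), antiviral (0.70), replication (0.78), mitosis (0.76) and proteasome lists (0.24) upward. The differentiation (-1.91), activated keratinocyte (-1.25) and cell junction lists (-0.49) passed downward. All 8 had an adjusted p of at least 0.907 with an estimated correlation.

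The count of genes over the 4 time points was 1 for the real groups. Of 100 regroupings of the 9 arrays (of 126 possible), 7 gave as many, the real one included. The others that did so are themselves built from differences between treated and untreated arrays. This test therefore cannot decide whether chance gives the count. The highest other count was 220, from regroupings that, with time as a block, contrast treated with untreated arrays at 4 h and 24 h alone. Of the 6 others, 4 carry the treatment in this way at 2 of the times, and 2 set the differences at 4 h and 48 h against each other. At an unadjusted p below 0.05 the real groups gave 1070 genes and the highest other regrouping 985. As 1 of 100 regroupings, the real one, reached it, a chance split rarely gave such a count, though 100 regroupings cannot exclude one. Some regroupings repeat the same contrast with its sign turned, so fewer than 100 distinct contrasts were tried. The real groups were also scanned on separate days as far as known, so the count cannot be credited to treatment alone.

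Differentiation and cell division ratios did not follow the order of the treatment times. MHC class II, NF-kB and complement medians also fell from 24 h to 48 h (3.04 to -0.38, 1.40 to 0.10 and 2.39 to 0.55). The antiviral median did not fall (1.14 and 1.19). Time courses of the immune lists thus rest on the same labels of the treated arrays. Poorer RNA of the treated 48 h array is argued against by its GAPDH 3' over 5' ratio of 1.10, inside the range of the others, while a part of the untreated 48 h array, whose 18S rRNA probe read 696.4, stays open. Quantile normalization is argued against too, as the 48 h differentiation median was -3.52 without it and -3.04 with values as deposited. Scaling made before deposit could not be tested, because the deposited arrays already shared a trimmed mean of about 150. Exchanged time labels among treated arrays may account for the order of the ratios. By 4279 genes outside the lists, 9 of 24 assignments of times matched the untreated arrays at least as well as the labels as given. The mean correlation was 0.02 as given and 0.27 at best. Counts of late calls could not decide for or against exchanged labels, since 5 of 6 exchanges of 2 labels gave over 1.5 times the 7 calls as given. The highest had 857 and 800. The exchange with 857 also gave 963 early and 1014 late-minus-early calls, against 1 and 0 as given. The other exchanges gave at most 1 early and 83 late-minus-early calls. That exchange thus stood apart in these counts, though it was picked as the highest of 6. Of the 6, 2 pair the same treated arrays as it does, itself included. A difference of the treated cultures was not tested.

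The interferon lists were higher on treated arrays, all scanned on 1 day, while 4 of the 5 untreated arrays were scanned on another. Scan day as the cause would raise the lists alike on every treated array, and the core median of 0.30 at 1 h, against 2.81 at 4 h and 2.73 at 24 h, argues against that. IRF1 was already 8.69-fold higher at 1 h, and for this gene treatment and scan day cannot be told apart, because no known scan day held both groups.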

How the results depend on the processing

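The fit without the treated 4 h and 48 h arrays was chosen after the data had been seen. The 7 genes that passed a test kept their direction in every setting run, and no other single gene was run through the settings. The call of IRF1 held in 12 (all times), 12 (early) and 13 (late) of 13 settings that kept all arrays, and in 9, 4 and 6 of 10 that left arrays out. Of the same 13 and 10, the late calls held for IFIT3 in 10 and 4, IFIT2 in 8 and 5, IGFBP5 in 10 and 4, WNT4, ETV4 and BCAM in 9 each and in 4, 4 and 1. ETV4 in untreated cells held in 11 of 12 and 9 of 10. The counts of 1 (all times), 1 (early), 7 (late, 4 higher and 3 lower), 0 (late minus early) and 1 (untreated time) moved as follows, in that order where several are given. Late calls were 22 with trimmed-mean scaling (11 higher, 11 lower), 16 with median scaling (12 higher, 4 lower) and 46 with values as deposited (20 higher, 26 lower). Median scaling also gave 3 for all times and moved the median of all genes to 0.13 for all times, 0.21 late and 0.12 for late minus early, and values as deposited gave 6 for untreated time, all 6 higher against 1 lower before. All times had 4 genes with a floor of 25, 2 with 50 added before the log, 3 with the median over probe sets and 4 without a trend in eBayes. Late had 1 with 50 added, 15 with every probe set (untreated time 3), 1 without a trend and 17 with robust eBayes. Without a filter the counts were 0, 0, 3, 2 and 10 (unadjusted 1161 and 364 for the first 2). Without the time block all times had 17 and late 75. Without the treated 4 h and 48 h arrays the counts were 0, 0, 3, 0 and 132 (limma, unadjusted 502, 290, 983, 605 and 1157). Leaving out 1 array at a time gave 1 to 181, 0 to 3, 0 to 66, 0 to 0 and 0 to 19, where an arm left with 1 array is assumed to vary like the others. The cause was not tested.

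The numbers of lists that passed, 10, 9, 9, 8 and 6 in the same order, were 0, 0, 0, 0 and 0 with an estimated correlation and also with fry. Leaving out 1 array at a time gave 6 to 11, 2 to 12, 8 to 11, 6 to 13 and 4 to 7 lists, and 3 early lists passed without the treated 4 h and 48 h arrays. In all 10 settings that left arrays out, camera calls held for the core list (all times, early and late), the antiviral list (all times and late), and chemokines and MHC class I (all times). In untreated cells they held for differentiation, replication and mitosis. The late call of the differentiation list held in 7 of 10, and its late-minus-early and all-times calls in 8 of 10. That fit turned the early means of MHC class I (-0.0571), NF-kB targets (-0.00228), mitosis (0.15) and ribosomal proteins (0.0111). It also turned the late-minus-early means of activated keratinocyte genes (0.26), replication (-0.93), mitosis (-1.85), cell junctions (0.28) and proteasome subunits (-0.13). With 1 array left out, means that turned ran early from -0.0564 to 1.74 for MHC class I, -1.34 to 0.16 for mitosis and -0.29 to 0.0109 for ribosomal proteins, and late from -0.45 to 0.0404 for ribosomal proteins. Late minus early they ran from -0.45 to 2.01 for replication, -1.21 to 2.68 for mitosis, -0.0113 to 0.48 for proteasome subunits and -0.38 to 2.22 for the core list. The core median at 24 h was 3.23 with trimmed-mean scaling against 2.73. With the mean of all untreated arrays as reference, the differentiation median was -1.33, -0.41, 0.63 and -1.38 at 1, 4, 24 and 48 h, against -0.41, 0.43, -0.26 and -3.43 with the array of the same time. The mitosis median moved to 0.65, -0.82 and 0.75 at 1, 4 and 48 h, from 0.08, -1.31 and 2.30. A fit with scan day as a block could not be made, because each known scan day held 1 group. Signal limits the dim genes: the floor of 100 hid any change below 30.02 deposited units.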

Other observations

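The values below were chosen after they had been seen where a gene is not among those fixed by rule. The alarmin genes S100A8 and S100A9, made by stressed keratinocytes, were 15.7-fold and 29.1-fold higher at 4 h, and 15.7-fold and at least 13.1-fold lower at 48 h, where untreated arrays read 6311 and 1313. Neither passed over the 4 time points (limma adjusted p = 0.709 and 0.675). The matrix protease genes MMP9 and MMP1 were at least 21.5-fold and 9.20-fold higher at 4 h, and PLAUR, the urokinase receptor, 6.37-fold higher. TGFBI, an extracellular matrix protein, was 3.41-fold lower at 4 h and 7.51-fold lower at 24 h, and the tight junction gene CLDN7 13.4-fold and 11.5-fold higher. The matrix protease list (19 measured, camera adjusted p = 0.124) did not pass.

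The lists that follow did not pass over the 4 time points. The basal layer list (15 measured, mean log2 -0.25, camera adjusted p = 0.578) held BCAM, and in this list KRT15 was 6.62-fold and 14.3-fold lower at 4 h and 24 h and the hemidesmosome gene DST 7.47-fold and 6.02-fold lower. ITGB4, its integrin partner, was 2.45-fold higher at 24 h, and another of its probe sets went the opposite way. Sterol synthesis genes (19 measured, camera adjusted p = 0.860) held FDPS, which was 2.58-fold higher at 48 h, and SCD, which was 2.25-fold lower. INSIG1, a brake on sterol synthesis, read 443.4 on the untreated and 2659 on the treated 48 h array. Heat shock and unfolded protein genes (15 measured, camera adjusted p = 0.578) and immediate early genes (19 measured, camera adjusted p = 0.976) did not pass. Here HSPA5 was 3.61-fold higher at 4 h, PDIA6 1.77-fold to 2.07-fold higher at each time, and FOS 7.22-fold lower at 4 h.

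CYP1A1 read 2674 on the untreated 4 h array and 3528 on the treated 48 h array, and 298.4 or less on the other 7. Across genes, arrays correlated at a Spearman coefficient of 0.943 between treated 4 h and 24 h, 0.941 between treated 1 h and 48 h, and 0.952 between the 2 untreated 1 h arrays.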
